A study of Mus musculus with 4 samples.

How the data were processed

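Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in hair follicle stem cells sorted from the back skin of male mice at postnatal day 70, during the second telogen, the resting phase of the hair cycle. Per the labels, 2 wild-type (WT) mice, numbers 13 and 15, carried floxed Nfib and Nfix alleles and no Cre, and 2 knockout mice (dKO), numbers 14 and 16, also carried Sox9-CreER. Live cells negative for Sca-1 and positive for integrin alpha 6 and CD34 were taken from all 4 mice, and dKO cells were in addition positive for the YFP reporter of Cre activity, so the sort gates of the genotypes differed by this marker. Libraries were read as 50 bp pairs, per the labels.

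Bowtie2 2.2.9, Picard and MACS2 are named in the submitters' processing notes, which give them no role or order, and the builds named there are mm10 and GRCm38. The deposited peak tables have the column layout of MACS2, per the file headers. The labels assign the same table to both mice of a genotype, so there was 1 list per genotype, and how the mice were combined, whether reads were shifted for the transposase and how duplicates were treated are not given in the sources used here. The signal column of the authors is the pileup at the peak summit in whole reads or fragments, not scaled for depth. The fold column deposited by the authors is the ratio of pileup plus 1 to local background plus 1. The −log10 p and −log10 q columns are the authors' peak significance. Their header cells were damaged by a spreadsheet program, and the columns were identified by position and by recomputing the Poisson p value from pileup and background, which matched the deposited −log10 p within 0.001 for 99.99% of 62807 WT and 99.997% of 62822 dKO peaks with −log10 p below 250. The lowest −log10 q was 1.30 in both lists, which is a q value of 0.05.

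Peaks of both lists that overlapped by at least 1 bp were joined into regions, each classed as WT-only, dKO-only or shared. Mitochondrial peaks, 5 in the WT list and 3 in the dKO list, were left out. Each region midpoint was placed at a gene end (within 1 kb of either end of a protein-coding gene), inside a gene body, or between genes, using a RefSeq gene table of GRCm38.p6, the assembly that mm10 names. This table has no strand, exons or sequence. The design had called for transcription start sites, exon classes and motif searches, and these were replaced by gene ends and gene bodies or not run. The exons removed by Cre were not analysed here. Regions were assigned to the nearest protein-coding gene body within 100 kb, which placed 70878 regions on 15629 of 21883 genes, and 8244 regions lay further away. Clusters were runs of at least 5 regions with gaps under 10 kb between midpoints.

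For each of 13 gene lists, fixed before the data were examined and holding 267 entries of which 265 matched a protein-coding gene, the net share was the number of WT-only minus dKO-only regions as a percent of the list's regions. It was set against 10000 random lists of the same size, matched on regions per gene in 20 bins at most, and a list was said to stand apart outside their central 95%. The comparisons of list overlap, gene ends and clusters were fixed before the data were examined. So were the gene lists, their test against random lists and the rule for named genes. The trend with gene density and the count of megabase windows were not among them. The rule names the NFI genes and Sox9, up to 2 genes per list and direction with a difference of at least 2 regions, the 8 genes with the largest net count in each direction among all genes, and the 4 regions of each class with the highest deposited −log10 q.

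With 1 list per genotype there is no spread between mice, and no p-value was computed for a difference between genotypes. Shares carry Wilson 95% intervals, and differences of shares normal 95% intervals, which cover counting error only and treat regions as independent. Deposited pileup, fold and −log10 values were used to describe, rank or filter peaks within a list. As a depth measure, the local background was recovered from pileup and fold. The alternatives were an overlap of 50% of the shorter peak, summits within 200 bp, a q value of 1e-05 or less, lists of equal length, single-list peaks from the stronger 50% of a list, gene ends within 2 kb, nearest genes within 20 kb, all genes within 10 kb, random lists matched also on strength, regions away from gene ends, and cluster gaps under 5 kb. After the data were seen, thinning of the WT list to a lower background and random lists matched on gene density were added.

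The overlap step gave the same number of overlapping peaks as bedtools 2.31.1, with a difference of 0 in either list. The gene-list step was tested on simulated data with the classes shuffled over the real regions of 15629 genes: 3.25% of 400 unchanged lists of 20 genes fell outside the central 95%. When 10%, 20% or 40% of the shared regions of 200 genes were made WT-only, 3, 7 and 9 of 10 lists of 20 genes lay above it. The shuffling removes any likeness of neighbouring regions in class, so these rates need not hold for the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.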

Results

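The accessible chromatin of hair follicle stem cells (HFSCs), the CD34-positive cells that rest in the bulge of the follicle between hair cycles, was compared between WT mice and mice with the genotype for Cre-driven deletion of Nfib and Nfix in Sox9-expressing cells and their descendants. NFIB and NFIX are transcription factors of the nuclear factor I family, and the comparison asks which open regions of these stem cells depend on them. There were 2 WT and 2 dKO mice, but the deposited data hold 1 peak list per genotype. The lists held 68197 WT and 63548 dKO peaks, with a median width of 768 bp in WT and 691 bp in dKO. The median deposited pileup at the summit was 73 in the WT list and 38 in the dKO list. The lowest local background, shared by 20494 WT peaks and 18496 dKO peaks, was 5.29 in the WT list and 2.73 in the dKO list, a ratio of 1.94, so the WT list was the more deeply sequenced if both were called with the same settings. No difference below has a replicate check, and the intervals given with shares are 95% Wilson intervals of counting error.

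Most open regions were found in both genotypes, and the WT list had more regions of its own than the dKO list. Of 79122 regions, 51129 were shared (64.6%, interval 64.3 to 65.0), 16743 were WT-only (21.2%, 20.9 to 21.4) and 11250 were dKO-only (14.2%, 13.98 to 14.46). A dKO peak overlapped 75.4% of WT peaks (75.1 to 75.8), and a WT peak overlapped 82.3% of dKO peaks (82.0 to 82.6). Single-genotype peaks were the weaker ones of each list. In the WT list the median deposited fold enrichment was 7.47 for shared and 4.13 for WT-only peaks, and in the dKO list 7.30 for shared and 4.29 for dKO-only peaks. Among the weakest 10% of WT peaks 38.0% had a dKO peak, against 99.7% of the strongest 10%. In the dKO list these shares were 47.8% and 99.97%. The stronger 50% of the WT list still held 2096 WT-only peaks and the stronger 50% of the dKO list 1065 dKO-only peaks. With lists of equal length there were 13735 WT-only and 12811 dKO-only regions, a ratio of 1.07 in place of 1.49. Equal lengths hold both counts close by construction, so this ratio does not show whether the excess is real. When the WT list was thinned to the dKO background, a setting added after the data were seen, there were 15002 WT-only and 12222 dKO-only regions. At 0.5 of that background, which makes the WT list the shallower of the lists, the order was the opposite, with 11719 WT-only and 15160 dKO-only regions.

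**Figure D1:**
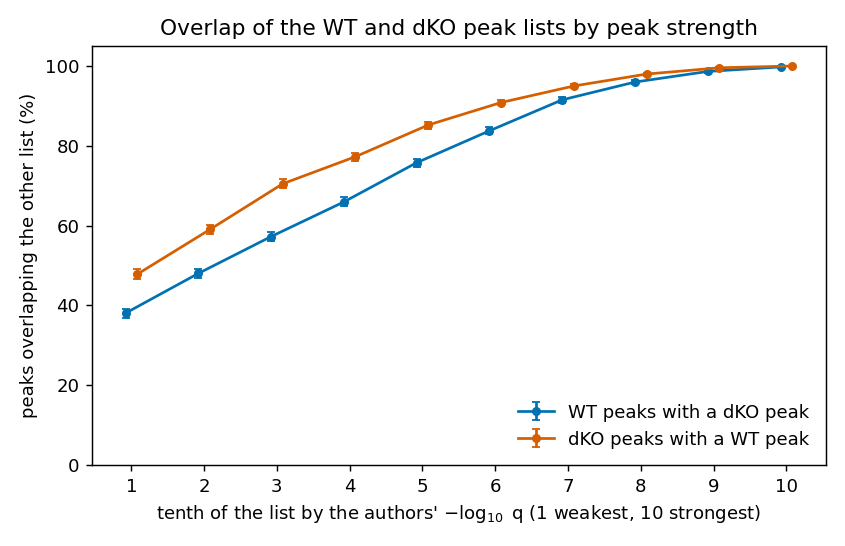
Percent of peaks of each list that overlap a peak of the other list (y axis) by steps of 10% of the list ranked on the authors' −log10 q (x axis, 1 weakest), with 95% Wilson intervals as error bars. The share rises from 38.0% to 99.7% in WT and from 47.8% to 99.97% in dKO.

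The strongest WT-only peak lay inside Siah3 on chromosome 14 (75472786 to 75474124, mm10) with a deposited −log10 q of 388.9. The next were on chromosome 18 (64104990 to 64105653), between genes with Wdr7 the nearest at 115.6 kb, on chromosome 3 (61041996 to 61043183), 33.6 kb from the purinergic receptor gene P2ry1, and on chromosome 18 (68692074 to 68692306), overlapping the long noncoding RNA gene Gm30821. The strongest dKO-only peak was 216 bp long and overlapped the pseudogene Gm10222 on chromosome 1 (24612630 to 24612845), with a −log10 q of 167.8. This stretch of chromosome 1 is known as a nuclear copy of mitochondrial DNA, which was not checked by sequence here, and the highest mitochondrial pileup was 13381 times the list's background in dKO and 5514 times in WT. The others lay between genes on chromosome 14 (86438099 to 86439354), 216.6 kb from Diaph3, on chromosome 6 (147784508 to 147786480), 152.9 kb from Ccdc91, and on chromosome 12 (116167479 to 116169197), 19.7 kb from Vipr2, which encodes a receptor for vasoactive intestinal peptide.

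At the NFI genes themselves, Nfia had more dKO-only than WT-only regions while the targeted genes had regions of both kinds in nearly equal number. Nfia (gene 18027, chromosome 4, 97578066 to 98118876) had 5 WT-only, 17 dKO-only and 19 shared regions. These counts were not scaled for gene length or gene density. Nfib (gene 18028, chromosome 4, 82290173 to 82506751) had 14 WT-only, 11 dKO-only and 55 shared regions, and Nfix (gene 18032, chromosome 8, 84704712 to 84801238) had 5, 4 and 16. Nfic (gene 18029, chromosome 10, 81396191 to 81431919) had 2 WT-only, 0 dKO-only and 8 shared regions. Sox9 (gene 20682, chromosome 11, 112782210 to 112787757), a regulator of HFSC identity whose promoter also drove the Cre, had 2 WT-only, 5 dKO-only and 7 shared regions. Peak lists do not show whether the floxed exons were lost.

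**Figure D2:**
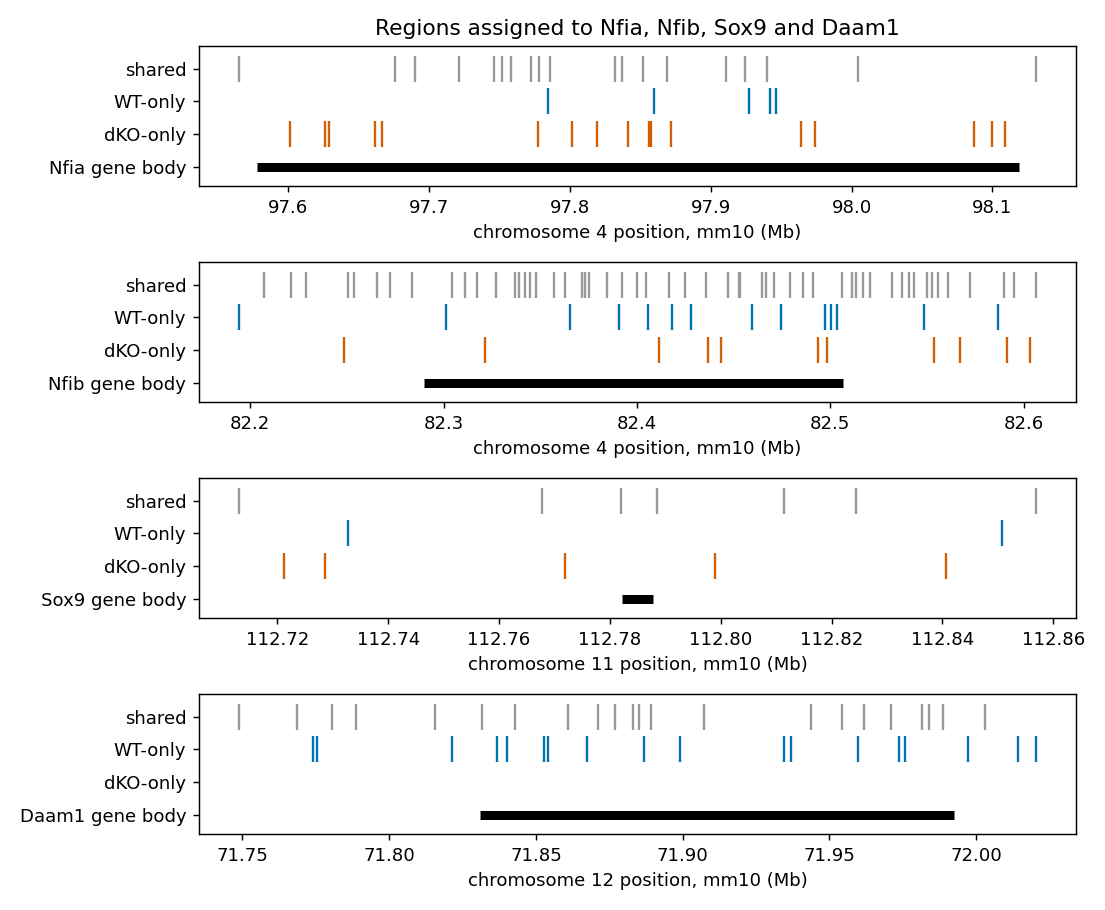
Positions (x axis, Mb in mm10) of shared, WT-only and dKO-only regions assigned to Nfia, Nfib, Sox9 and Daam1, each tick marking a region's midpoint, with the gene body as a black bar. The 17 dKO-only regions of Nfia lie inside its gene body, and the 18 WT-only regions of Daam1 lie inside and beside its own.

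The excess of WT-only over dKO-only regions was largest at Bnc2, Trabd2b and Daam1. Bnc2 (chromosome 4, 84266804 to 84676029), which encodes the zinc finger protein basonuclin 2, had 31 WT-only and 9 dKO-only regions. Trabd2b (chromosome 4, 114406682 to 114615098), encoding a protease that inactivates Wnt proteins, had 23 and 4. Daam1 (chromosome 12, 71830950 to 71992376), a formin that acts downstream of noncanonical Wnt signalling, had 18 WT-only and 0 dKO-only regions beside 22 shared ones. Hivep3 (chromosome 4, 119733759 to 120138045) had 18 and 1, and the E-protein gene Tcf12 (chromosome 9, 71844252 to 72111893) also had 18 and 1. Ptprg (chromosome 14, 11553440 to 12242041) had 19 and 4, and Cacna1c (chromosome 6, 118587240 to 119197384), a calcium channel gene, had 16 and 2. Ntrk2 (chromosome 13, 58806472 to 59133970), encoding the neurotrophin receptor TrkB, had 15 WT-only, 0 dKO-only and 4 shared regions.

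The excess of dKO-only over WT-only regions was largest at Rbfox1, Nkain2 and Egfem1. Rbfox1 (chromosome 16, 5884793 to 7412480), a neuronal splicing regulator, had 5 WT-only and 22 dKO-only regions. Nkain2 (chromosome 10, 31689310 to 32897174) had 0 and 15, and Egfem1 (chromosome 3, 29081653 to 29691058) had 0 and 14. Macrod2 (chromosome 2, 140395303 to 142392966) had 15 and 28, and Ctnnd2 (chromosome 15, 30172534 to 31029344), encoding the neural catenin delta 2, had 1 and 14. Nfia followed with the counts above. Adamtsl1 (chromosome 4, 85513852 to 86428390) had 8 and 19, and Naaladl2 (chromosome 3, 23798103 to 25144149) had 3 and 14. Genes in both directions were ranked by net count, which was not scaled for gene length or gene density. Away from gene ends, dKO-only regions exceeded WT-only regions where genes were fewest, at 23.0% against 21.2%. Where genes were most, they were fewer, at 10.2% against 26.6%. How far this trend gives the counts above was not tested.

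Genes of HFSC identity had a net share of 6.04% over 596 regions, at the 30.2 percentile of random lists, with 18 genes having more WT-only and 5 more dKO-only regions. Over all regions assigned to genes the net share was higher, at 8.35%, so a lean towards WT was not particular to this list. That of HFSC identity genes turned to −1.23% with lists of equal length. It was 1.73% with WT thinned to the dKO background and 13.3% at a q value of 1e-05 or less. Fgf18, a growth factor of the resting follicle, had 6 WT-only and 0 dKO-only regions, and the corepressor gene Tle4 had 7 and 2. Lhx2, a transcription factor of the bulge, had 0 WT-only, 3 dKO-only and 13 shared regions. The list of quiescence and BMP signalling genes had a net share of 12.97% (percentile 81.1), with 12 genes towards WT and 2 towards dKO. Foxp1, a transcription factor that restrains HFSC division, had 19 WT-only and 6 dKO-only regions, and Gdf10, a ligand of the TGF-beta family, had 7 and 2. Ltbp1 had 5 and 8, and the cell cycle inhibitor gene Cdkn1a had 0 and 2.

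The lists closest to the lower limit of the random lists were hair lineage genes, with a net share of −1.33% (percentile 6.63), and wound and stress genes, with 1.07% (percentile 7.59). Among hair lineage genes, Trps1, a transcription factor gene of hair development, had 1 WT-only and 10 dKO-only regions and Ctsc had 0 and 4, whereas Gata3 had 4 and 1 and Hoxc13, a regulator of hair keratins, 3 and 0. Among wound and stress genes, Tnc, encoding the matrix protein tenascin C, had 2 WT-only and 13 dKO-only regions and the EGF receptor ligand gene Areg had 0 and 3, whereas Myc had 6 and 0 and Ets2 had 5 and 1. Their numbers of genes in each direction were 8 towards WT and 6 towards dKO for hair lineage, and 10 and 10 for wound and stress. The hair lineage net share changed sign in 4 of 8 alternatives, from −8.51% with lists of equal length (percentile 5.2) to 10.3% at a q value of 1e-05 or less (percentile 29.7), and that of wound and stress genes in 3 of 8, from −4.02% with lists of equal length (percentile 13.5) to 6.72% at that q value (percentile 7.9). With WT thinned to the dKO background, the net shares were −8.45% (percentile 2.7) for hair lineage and −4.02% (percentile 4.7) for wound and stress genes, within the central 95%.

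Other epithelial programmes held members in both directions. Interfollicular epidermis and barrier genes had a net share of 2.67% (percentile 15.2): the transcription factor gene Ehf had 6 WT-only and 0 dKO-only regions and Klf4 had 4 and 2, while the transglutaminase gene Tgm3 had 2 and 6 and the desmoglein gene Dsg1a had 1 and 3. The net share of this list turned to −1.36% with lists of equal length and −0.671% with WT thinned to the dKO background, and was 11.03% at a q value of 1e-05 or less. Sebaceous gland genes had a net share of 7.21% (percentile 38.7), with Elovl6 at 5 and 1, Acsl1 at 2 and 0, and Prdm1 at 1 and 4. Upper follicle genes had 11.2% (percentile 65.0), with the stem cell receptor gene Lgr6 at 6 and 1, Lrig1 at 8 and 5, and Barx2 at 3 and 9. Hemidesmosome, junction and basal keratin genes had 7.40% (percentile 44.8). In that list Dst and Trp63, the latter encoding the master regulator p63 of stratified epithelia, both had 9 WT-only and 2 dKO-only regions, while Cd44 had 3 and 7 and Cd9 had 0 and 3. With lists of equal length the net share was 0.917% for sebaceous gland genes (percentile 39.0) and 3.01% for upper follicle genes (percentile 54.7). For hemidesmosome, junction and basal keratin genes it was 1.36% (percentile 53.6).

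Marker lists of other skin cells also lay within the range of random lists. The fibroblast list was nearest to the upper limit with a net share of 23.3% over 60 regions (percentile 94.7), where Col1a2 had 4 WT-only and 0 dKO-only regions, Col1a1 had 3 and 0, and Col3a1 had 0 and 2. Its net share was 9.52% with nearest genes within 20 kb (percentile 49.0), 7.90% with all genes within 10 kb (percentile 45.8) and 2.86% with single-list peaks from the stronger 50% (percentile 45.8). Under the other settings its percentile ran from 83.0 with lists of equal length to 96.3 with random lists matched on gene density. The melanocyte list had 10.6% (percentile 59.4), with Dct at 3 and 0 and Mitf at 7 and 5. Its net share turned to −3.28% with lists of equal length and −2.5% with single-list peaks from the stronger 50%. The endothelial list had 6.90% (percentile 41.5), with Kdr at 5 and 0, Tek at 4 and 1, and Cdh5 and Egfl7 each at 0 and 3. The immune list had 5.56% over 18 regions (percentile 41.1), with Ptprc at 0 and 3. Its net share turned to −6.25% and −8.33% under the same settings. Housekeeping genes had 16.7% over 42 regions (percentile 81.6), with Actb and Psmb4 each at 2 and 0. In total 0 of 13 lists lay outside the central 95%, where 0.65 would be expected by chance. With single-list peaks from the stronger 50% alone, the housekeeping list fell below it, with a net share of −6.45% (percentile 1.8). That value rests on at most 3 dKO-only regions, the number this list had in all.

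**Figure D3:**
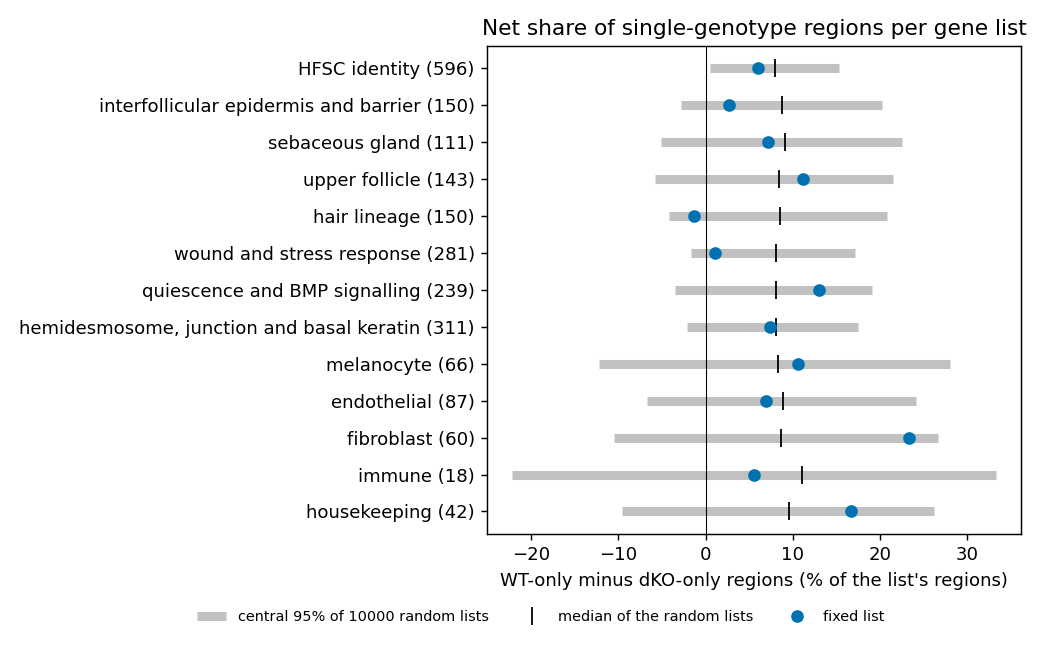
WT-only minus dKO-only regions as percent of each list's regions (x axis) for the 13 gene lists (y axis, with the number of regions), as blue points, with the median (black tick) and central 95% (grey bar) of 10000 random lists matched on regions per gene. All 13 points lie within their grey bars, from −1.33% for hair lineage to 23.3% for fibroblast genes.

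Regions at the ends of protein-coding genes were mostly common to both genotypes, and single-genotype regions lay within gene bodies and between genes. At gene ends 90.2% of 12769 regions were shared, 6.27% were WT-only (5.87 to 6.71) and 3.51% were dKO-only (3.20 to 3.84). Inside gene bodies 25.6% of 35043 regions were WT-only (25.1 to 26.0) and 14.3% dKO-only (13.98 to 14.71). Between genes 22.3% of 31310 regions were WT-only (21.8 to 22.8) and 18.4% dKO-only (18.0 to 18.9). Gene bodies therefore held 53.5% of WT-only and 44.7% of dKO-only regions. Gene ends carried stronger peaks, but in the middle 20% of WT strength 7.59% of gene-end regions lacked a dKO peak (6.27 to 9.15), against 20.4% inside genes (19.4 to 21.4) and 23.0% between genes (21.9 to 24.1). In the weakest 20% the WT-only share at gene ends was 49.1%, against 60.1% and 55.4%.

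In dense clusters of open regions, of which there were 3086 with at least 5 regions, dKO-only regions were fewer than among isolated regions. They made up 10.98% of 22817 clustered regions (10.6 to 11.4) and 18.0% of 22660 isolated ones (17.5 to 18.5). Within the middle 20% of dKO strength 6.94% of clustered regions (6.18 to 7.80) and 18.0% of isolated ones (16.7 to 19.4) lacked a WT peak. Clusters were not matched on gene density, with which the dKO-only share also fell. How far that trend gives this difference was not tested. The WT-only share was 21.9% in clusters (21.4 to 22.4) and 18.7% among isolated regions (18.2 to 19.2). Within strength bins this order held for the weakest 20% of WT regions, at 58.9% (57.5 to 60.4) against 54.6% (52.9 to 56.2), and was the opposite in the 3 bins above it, at 36.3% against 39.5%, 18.0% against 21.1% and 5.10% against 6.98%. In the strongest 20% the shares were 0.575% (0.372 to 0.886) and 0.734% (0.528 to 1.02), with overlapping intervals. With single-list peaks from the stronger 50% alone, the clustered minus isolated difference in the WT-only share was −1.15 percentage points. With cluster gaps under 5 kb, the clustered minus isolated difference in the dKO-only share shrank from −7.04 to −0.877 points, within its 95% counting error of 1.23.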

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

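The weighed tests on the overall excess of WT-only regions and on its stronger 50% were chosen after the result was seen. So were the test on mice and gates, the thinning settings and the split of single-list regions by gene density. The trend with gene density and the count of megabase windows were not among the comparisons fixed beforehand.

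Mitochondrial peaks were left out of all comparisons. The highest mitochondrial pileup was 13381 times the list's own background in dKO and 5514 times in WT.

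WT-only regions outnumbered dKO-only regions 1.49 to 1. Lower depth of the dKO list cannot be told apart from a loss of regions. After thinning WT to the dKO background the ratio was 1.23 and at 0.5 of that background 0.773. The true depths are open because the calling settings are not given in the sources used here. With lists of equal length the ratio was 1.07, but equal lengths hold both counts close whatever the cause, so this value decides nothing. In the stronger 50% of the WT list, where 2096 peaks had no dKO peak, thinning to 0.5 of the dKO background removed 0 of 34171 peaks, but the choice of these peaks by significance fixes that outcome, so it decides nothing. Differences between individual mice, or the YFP gate used for dKO cells alone, may also give single-list peaks, and with 1 list per genotype these cannot be told apart from an effect of the deletions. Sox9-CreER was likewise carried by dKO mice alone, so an effect of carrying it cannot be told apart either.

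The balance of WT-only and dKO-only regions followed gene density. Away from gene ends, the WT-only share rose from 21.2% (20.5 to 21.8) to 26.6% (25.8 to 27.3) and the dKO-only share fell from 23.0% (22.3 to 23.7) to 10.2% (9.69 to 10.7) from the fifth of regions with fewest genes within 1 Mb to the fifth with most, a difference in net share of 18.2 percentage points (normal 95% interval 16.7 to 19.6). The difference was 18.9 points after thinning WT to the dKO background and 20.3 points at 0.5 of it. Thinning takes peaks from the WT list only, 2760 and 9033 of 68192, and cannot remove a dKO-only region. Loss of these weaker WT peaks thus did not shrink the difference. Whether lower depth of the dKO list contributes to it is not decided, because the dKO-only share carries much of the trend. Between the stronger 50% of both lists the difference was 20.9 points, but this setting cannot decide whether weak peaks give the trend. It counts a peak as single-list when its partner lies in the other list's weaker 50%. It held 2993 single-list regions where genes were fewest and 2209 where they were most. With single-list peaks from the stronger 50% alone there were 841 and 502, and these fewer regions shrink the net difference to 4.38 points. Of them, WT-only regions made up 48.3% (44.9 to 51.7) where genes were fewest and 84.9% (81.5 to 87.7) where they were most. The balance among strong single-list peaks thus followed gene density too. A base composition bias between the libraries could give such a trend and cannot be told apart from it, because 0 regions had a GC value without a genome sequence, and a change of chromatin with genotype stays open too.

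Single-genotype regions were gathered in certain megabases. In 215 of 2339 windows of 1 Mb the net count was at least 12 in either direction, against a median of 107 and at most 128 windows in 1000 shuffles of the classes among regions of like strength, gene density and position at gene ends, which argues against chance placement for the number of such windows. Towards dKO there were 23 such windows, against at most 8 in the shuffles, and towards WT 192, against at most 125. The largest single net counts, 32 towards WT and 21 towards dKO, did not exceed the largest in all 1000 shuffles together, 38 and 27. How many shuffles reached 32 or 21 was not counted, so this does not show how unusual these windows are. The shuffles treat regions as exchangeable, and whether neighbouring regions change together because of genotype, base composition or differences between mice was not tested.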

How the results depend on the processing

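No paired analysis was possible because the mice of the genotypes share no numbers and each genotype has 1 list. For the same reason no mouse could be left out. Motif settings were not run. Of 130 percentiles of the 13 gene lists under alternatives, 129 stayed inside the central 95%. All 13 lay inside it at first, and most values would fall there by chance, so this count says little about stability. Of 104 net shares under settings that can move them, 15 changed sign, in 7 lists. Those were HFSC identity, −1.23% with equal lists against 6.04%, and the epidermis, hair lineage, wound and stress, melanocyte (−3.28% against 10.6%), immune and housekeeping lists. Equal lists also lowered the excess over all regions, from 6.94% to 1.21%, and the stricter q value raised it to 12.4%. Such a common shift can by itself turn the sign of a list near 0. The percentile exception was the housekeeping list with single-list peaks from the stronger 50%, at percentile 1.8, which rests on at most 3 dKO-only regions. The cause of the changes below was not tested except where the setting itself removes peaks. Thinning was chosen after the data were seen.

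The excess of WT-only over dKO-only regions, 6.94% of regions, was 12.4% at a q value of 1e-05 or less, 5.43% with summits within 200 bp, 1.21% with lists of equal length, 1.90% with single-list peaks from the stronger 50% and 3.59% with WT thinned to the dKO background. It turned to −4.64% at 0.5 of that background. Lists of equal length hold both counts close by construction. At the stricter q value dKO-only regions fell from 11250 to 8006, while WT-only regions went from 16743 to 16778. A shared region becomes WT-only where only its dKO peak misses the cut. The rise to 12.4% thus does not show a larger difference between genotypes. Summits gave 17359 dKO-only regions, and the stronger 50% 2096 WT-only and 1065 dKO-only regions. The latter setting kept all 51129 shared regions, so a share of all regions shrinks by construction. Its 1.90% thus does not show a weaker imbalance among strong single-list peaks.

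Away from gene ends minus at gene ends, the shares differed by 17.8 points for WT-only and 12.8 for dKO-only regions. The differences were 20.6 and 10.4 at the stricter q value, 15.6 and 14.7 with equal lists, and 4.12 and 2.28 in the stronger 50%. They were 14.5 and 11.9 with gene ends of 2 kb, and 16.6 and 14.04 after thinning to the dKO background. Keeping all shared regions makes the values in the stronger 50% small by construction.

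Clustered minus isolated, the shares differed by 3.18 points for WT-only and −7.04 for dKO-only regions. The differences were 2.33 and −6.28 at the stricter q value, 1.08 and −6.30 with equal lists, −1.15 and −2.39 in the stronger 50%, and 4.78 and −0.877 with gaps under 5 kb, and the WT-only difference was 1.84 after thinning. Keeping all shared regions also makes the sizes in the stronger 50% small by construction. Depth per mouse is unknown, and which weak peaks it kept out of either list was not tested.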

Other observations

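The genes, windows and families here were chosen after their values were seen. The largest net counts per window, 21 towards dKO and 32 towards WT, did not exceed the largest in 1000 shuffles of the classes. How many shuffles reached them was not counted. The 1 Mb window with the largest excess of dKO-only regions was on chromosome 5 (86000001 to 87000000), with 0 WT-only, 21 dKO-only and 14 shared regions. It holds the Tmprss11 genes, a cluster of membrane-bound serine proteases of stratified epithelia, and Tmprss11a had 0 WT-only and 8 dKO-only regions. A window on chromosome 2 (12000001 to 13000000) with Itga8, the integrin alpha 8 gene, had 1 WT-only and 19 dKO-only regions. The window with part of Tnc on chromosome 4 (64000001 to 65000000) had 4 and 22, and that of Tsc22d1 on chromosome 14 (76000001 to 77000000) had 5 and 21. Dkk2, which encodes a Wnt antagonist, had 0 WT-only, 10 dKO-only and 1 shared region.

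Towards WT, the largest excess was on chromosome 4 (119000001 to 120000000), in a window with Slc2a1, Foxj3 and Hivep3, where 34 regions were WT-only and 2 dKO-only. A window on chromosome 13 (97000001 to 98000000) with Arhgef28 and Enc1 had 32 and 4. The window of Lmx1b, a LIM homeodomain gene, on chromosome 2 (33000001 to 34000000) had 26 and 0. A window on chromosome 6 (52000001 to 53000000) with Skap2, Jazf1, Hibadh, Tax1bp1, Evx1 and the Hoxa genes had 30 and 6. The Hoxa genes together had only 7 and 3 (percentile 65.6 of random lists), so most of its WT-only regions were assigned to other genes.

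Gene families were scanned by the letters that begin their symbols. Of 260 families with at least 8 genes, 16 lay outside the central 95% of random lists, against 13 expected by chance, so the scan as a whole gave little beyond chance. The family furthest towards dKO was Tmprss, at percentile 0.020 with 8 WT-only and 22 dKO-only regions, most of the latter in the window on chromosome 5. It was followed by the Sema family of axon guidance ligands, with 29 and 44 (percentile 0.670), and the Rbm family, with 7 and 17 (percentile 0.690). Furthest towards WT were the Ifi family, with 11 and 1 (percentile 99.8), the Rnf family, with 86 and 24 (percentile 99.7), and the Nat family, with 10 and 2 (percentile 99.6).

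By chromosome, the WT-only share was highest among the autosomes on chromosomes 4, at 23.9%, and 11, at 23.8%, and the dKO-only share was lowest among them on chromosome 11, at 10.6%. The X chromosome had the highest dKO-only share, at 16.7%.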
